A study of Sus scrofa with 10 samples.

How the data were processed

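RNA from the hypothalamus of 10 backcross pigs (Iberian x Landrace) was sequenced, 5 animals of high growth and fatness and 5 of low growth and fatness. Per the labels' protocols, RNA was extracted with a RiboPure kit, paired-end libraries were made with an Illumina TruSeq RNA kit, and libraries shared lanes of a HiSeq 2000. Which animal ran in which lane was not given in the sources used here, so lanes could not be compared with groups. The submitters' processing notes name CASAVA, FastQC, Trim Galore, TopHat2 2.0.5, Bowtie2, Cufflinks 2.0.2 and the pig genome build Sscrofa10.2, without saying how each was run.

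The values analysed are FPKM (fragment counts scaled for transcript length and library size), which the authors deposited as 1 value per gene row and group, with a lower and an upper confidence bound and a status, per the file headers. The group values were used as the authors' values. The confidence level of the bounds was not given in the sources used here. Values per animal were not analysed here. Read counts were not used either, so the depth of each sample is unknown. The median half-width of the interval was 39.3% of the value in the high group and 45.1% in the low group. Of rows at 20 FPKM or more, 58.1% in the high group and 60.4% in the low group had a half-width within 10% of a common floor, so the level of a gene largely set the width.

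The table held 25009 gene rows with Ensembl identifiers. Of these, 16804 carried a gene name, 963 were named from a reference table of identifiers and 7242 stayed unnamed. Rows without an estimate in at least 1 group (58 rows) were left out, whatever value they carried. GFAP, listed at 0 in both groups, was among them. Rows with a mean of at least 1 FPKM over both groups numbered 15281, and 15156 of them had a value above 0 in both groups. Differences are log2(FPKM + 1) of the high group minus that of the low group, a scale that understates the change of low genes. Coordinates are those of the file, counted from 1.

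Before the data were examined, a limma fit, camera set tests and exact permutation tests over 10 animals had been planned, together with the gene lists and the rule for naming genes. None of these tests could be run on 1 value per group. What took their place was chosen after the data had been seen. The first replacement called a gene where the deposited intervals did not overlap, and gave 70 rows. It was then exchanged for a z value, the difference of natural logs over its spread with each half-width taken as 2 SD, two-sided, with Benjamini-Hochberg adjustment at 0.05, which gave 32 rows. The exchange was made after both counts and the genes behind them were known. The reasons were a simulation, in which non-overlap alone called 72 of 14956 unchanged rows and z called 0, and the adjustment at 0.05 that had been planned. All 32 rows are among the 70. In all, 6 ways of calling rows were computed on the deposited values: z at 0.05 and at 0.10 (40 rows), non-overlap with and without an FPKM ratio of at least 2 (70 rows each, as the ratio removed no row and so checked nothing), and z and non-overlap with 1 row per symbol on placed chromosomes (26 and 54 rows). Non-overlap was also computed on scaled values. The z value rests on the authors' bounds, is not a test across animals and gives no replicate check.

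In simulated data built from the deposited levels and widths, with 200 changed rows among 15156, z recovered 0% of 1.5-fold, 14% of 2-fold, 56% of 4-fold and 82% of 8-fold changes. The simulation took the bounds as 2 SD, as z does, and only z was adjusted. It could therefore not show which rule suits the real bounds. Over the real rows the SD of z was 0.71, so the simulated noise was larger than the spread of the real differences and its 72 calls are no measure of how many of the 70 are chance. Of tested rows, 2.11% had an absolute z above 1.96.

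For 30 gene lists fixed in advance (17 pathways and 13 cell types), the median difference of the tested members was set against the medians of 10000 random lists of the same size, drawn from 20 bins of level. A median below the 2.5th or above the 97.5th percentile was taken as outside. This describes these group values only and ignores that genes of a list vary together. By chance 1.5 of 30 lists would be outside if genes and lists were independent. In 100 random lists of 12 rows, 6 were outside, which does not test lists of related genes.

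The rule for naming genes was kept. It takes the 10 largest differences in each direction among genes with a symbol past the threshold, at most 12 list members past it when adjusted over the list alone, and a fixed set of hypothalamic, pituitary and choroid plexus genes whatever their result. FOS, EGR1, ALAS2 and the myelin genes MOBP, UGT8, CLDN11 and ERMN lie outside the rule and were named after their values were seen, to show the members behind a count. GH1 of the fixed set was not matched to a row. Alternatives were other pseudocounts (0.1 and 0.5), no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a threshold of 0.10 and, added after the data were seen, the other calling rules, list means and lists without called members. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.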

Results

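Gene levels in the hypothalamus, the brain region that controls appetite, growth and pituitary hormones, were compared between 5 pigs of high and 5 pigs of low growth and fatness. Each gene had 1 FPKM value per group with deposited bounds, given in parentheses where printed, and there was no replicate check. The depth of each sample is unknown. The median of tested rows was 7.08 FPKM in the high group and 7.60 FPKM in the low group, and the median log2 difference (high minus low) was -0.10. Of 15281 tested rows, 10349 were higher in the low group and 4932 in the high group. Counts of list members by direction should be read against that share.

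The comparison asked which hypothalamic genes differ between pigs that diverge in growth and fatness. Of the genes past the threshold, AGXT2 was the exception to a higher value in the low group. COL3A1, a fibrillar collagen chain, was at 21.5 FPKM (11.6 to 31.5) in the low group and 4.20 FPKM (2.73 to 5.66) in the high group. CRABP2, a retinoic acid binding protein, was at 22.5 FPKM (10.6 to 34.5) against 2.12 FPKM (0.647 to 3.59). The chemokine CCL2 was at 20.7 against 4.52 FPKM, and LCN2, an iron-siderophore binding protein of innate immunity, at 37.3 against 8.77 FPKM. AGXT2, a mitochondrial aminotransferase, was at 6.72 FPKM (3.31 to 10.1) in the high group and 1.03 FPKM (0.406 to 1.65) in the low group.

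In all, 32 of 15156 rows passed an adjusted threshold of 0.05 in a z test built from the deposited bounds, 31 higher in the low group and 1 higher in the high group. Intervals that did not overlap, the rule used first, gave 70 rows, 66 and 4. In simulated unchanged rows with each half-width taken as 2 SD, that looser rule gave 72 calls and z gave 0, though the SD of z over the real rows was 0.71, below that of the simulation's premise. The simulation shared the premise of z and only z was adjusted, so it could not decide between the rules. The choice of z was made after both counts were seen. The low-to-high FPKM ratio of the 31 rows ran from 2.65 to 27.2, with a median of 5.13. After median-of-ratios scaling or quantile normalization 19 rows passed, and CCL2 was not among them, at log2 differences of -1.87 under both against -1.97. With a filter at a mean of at least 5 FPKM, 0 rows passed as higher in the high group, since AGXT2 has a mean of 3.87 FPKM.

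The other genes named among the largest differences were also higher in the low group. C16orf89 was at 11.6 against 0.637 FPKM, MPZL2, a cell adhesion protein, at 6.88 against 0.887 FPKM, and C7, a complement component, at 7.87 against 1.05 FPKM. AEBP1 was at 14.5 against 2.88 FPKM and ISLR at 11.8 against 2.39 FPKM. SLC22A8, an organic anion transporter, was at 3.23 against 0.119 FPKM. On build Sscrofa10.2, COL3A1 (ENSSSCG00000016034) lies on chromosome 15 (104067018 to 104105776), CRABP2 on chromosome 4 (101959961 to 101966042), C16orf89 on chromosome 3 (38352516 to 38371018) and AGXT2 (ENSSSCG00000016829) on chromosome 16 (21478635 to 21519015).

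**Figure D1:**
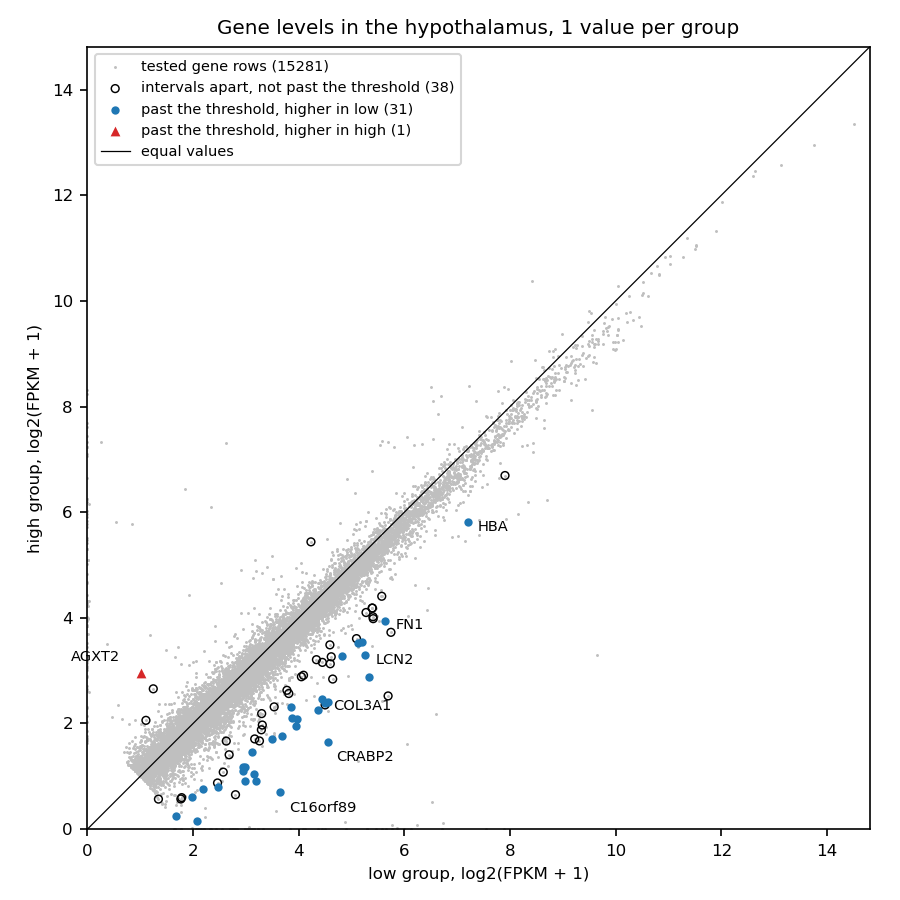
Each point is a gene row, with its log2(FPKM + 1) in the low group on the x axis and in the high group on the y axis. Filled blue points mark the 31 rows past the threshold that were higher in the low group, the red triangle AGXT2, and open circles rows whose intervals did not overlap but that missed the threshold.

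Markers of mural cells, fibroblasts and meninges had the lowest list median, -1.23, against -0.25 to 0.02 in random lists of matched level. All 12 tested members had lower values in the high group. Over all rows 2 of them passed, COL3A1 and the smooth muscle actin ACTA2 (8.68 against 27.4 FPKM), which missed the threshold after quantile normalization. Adjusted over the list alone, 9 passed, among them COL1A2 (15.2 against 41.4 FPKM), DCN (7.91 against 20.8 FPKM) and COL1A1 (12.2 against 52.6 FPKM). Here and below, adjustment over a list alone does not correct for the 30 lists, some of which share members. COL1A1 has 2 rows in this annotation, so its reads may be split and its values are uncertain. The row not used for the list, on an unplaced scaffold, passed over all rows (3.26 against 14.5 FPKM). Beside the COL1A1 rows lie 4 unnamed rows whose intervals did not overlap (log2 differences -2.46 to -2.12). Of these, ENSSSCG00000021943, ENSSSCG00000029074 and ENSSSCG00000021015 passed over all rows, so the 32 rows past the threshold may count 1 gene several times.

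Immediate early genes, which are transcribed rapidly after stimulation, had a median of -0.87 (random lists -0.28 to 0.07), and 0 of 9 tested members had the higher value in the high group. BTG2 (10.5 against 33.7 FPKM) passed over all rows. Adjusted over the list alone 5 passed, including JUNB (2.68 against 8.80 FPKM), FOS (34.8 against 64.4 FPKM) and EGR1 (18.8 against 35.9 FPKM).

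Immune lists had lower medians in the high group as well. Antigen presentation genes had a median of -0.60 (random lists -0.26 to 0.02), and 2 of 12 passed adjusted over the list alone, 0 over all rows. These were the class II chains SLA-DQA1 (14.8 against 41.5 FPKM) and SLA-DQB1 (11.2 against 33.1 FPKM), which belong to a family of similar genes and are uncertain. Interferon-stimulated genes had a median of -0.45 (random lists -0.22 to 0.02), with 0 of 17 past either adjustment. The microglial list had a median of -0.53 (random lists -0.31 to -0.01), with 0 of 11 past either adjustment.

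Oligodendrocyte and myelin genes had a median of -0.63 (random lists -0.37 to -0.08). Adjusted over the list alone 4 of 12 passed, MOBP (367 against 685 FPKM), UGT8 (57.0 against 106 FPKM), CLDN11 (153 against 317 FPKM) and ERMN (83.7 against 150 FPKM), and 0 passed over all rows. Oligodendrocyte precursor genes had a median of -0.52 (random lists -0.28 to 0.07), with 0 of 8 past either adjustment. Judged by the mean of the members in place of the median, the myelin list (-0.70) and the microglial list (-0.50) were inside the range of the means of random lists.

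Markers of tissue next to the hypothalamus moved with the group too. The anterior pituitary list had a median of -0.96 (random lists -0.37 to 0.04) over 6 of its 11 members in the file, and of -0.39 without the filter on low values. Within it CGA, the alpha subunit of pituitary glycoprotein hormones, passed adjusted over the list alone, at 15.5 against 43.7 FPKM, whereas the interval of prolactin, PRL, was wide (279 FPKM, 174 to 384, against 570 FPKM, 102 to 1039). The blood list had a median of -1.01 (random lists -0.28 to 0.09). Adjusted over the list alone 6 of 8 passed, including HBB (102 against 239 FPKM) and ALAS2 (1.85 against 5.07 FPKM), and 0 list members passed over all rows. A haemoglobin alpha row named HBA, which the list's symbols did not match, did pass over all rows, at 55.0 against 146 FPKM. It was named after its values were seen. The choroid plexus list had a median of -0.48 (random lists -0.29 to 0.09). IGFBP2 (6.16 against 24.0 FPKM) passed adjusted over that list, and transthyretin, TTR, was at 268 against 407 FPKM with overlapping intervals.

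None of the appetite peptides or their receptors in the fixed lists passed, over all rows or adjusted over the list alone. In the simulation z over all rows recovered 0% of 1.5-fold and 14% of 2-fold changes, so a gene that missed may still differ by that much. POMC, the precursor of the appetite-restraining melanocortins, was at 84.0 FPKM (51.3 to 117) in the high group and 110 FPKM (65.9 to 155) in the low group. POMC is also a member of the anterior pituitary list (median -0.96), so its value cannot be assigned to appetite neurons alone. NPY was at 7.25 against 11.9 FPKM and AGRP at 7.74 against 8.81 FPKM, both appetite-stimulating peptides. CARTPT was at 115 FPKM (81.6 to 149) against 70.2 FPKM (42.0 to 98.4), and PMCH, the precursor of melanin-concentrating hormone, at 167 FPKM (120 to 215) against 91.8 FPKM (51.5 to 132). HCRT was at 4.16 against 1.78 FPKM and the melanocortin receptor MC4R at 2.22 against 1.41 FPKM. The leptin receptor LEPR, at 0.597 against 1.20 FPKM, was below the filter.

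The feeding-stimulating list had a median of 0.21 (random lists -0.25 to 0.08) and the feeding-restraining list -0.01 (random lists -0.25 to 0.04), which was above the range without the filter (0.06) and after quantile normalization (0.14). The magnocellular list had a median of 0.14 (random lists -0.42 to -0.02). Of its 6 members 4, PCSK1, PCSK2, SCG2 and CHGB, are also in the prohormone list, so these lists are not independent, and PCSK2 (0.03) and SCG2 (0.24) set the median. Its peptides vasopressin, AVP, and oxytocin, OXT, were at 472 against 354 FPKM and at 55.5 against 34.7 FPKM. Hypothalamic transcription factors had a median of 0.21 (random lists -0.23 to 0.13) over 9 of 15 members, which turned to -0.013 without the filter. Medians were lower for prohormone processing genes, 0.02 (random lists -0.34 to -0.06), and GABA and glutamate neuron genes, 0.07 (random lists -0.32 to 0.06). After median-of-ratios scaling the medians of the magnocellular, transcription factor, prohormone and GABA and glutamate lists were 0.25, 0.32, 0.13 and 0.18. No member of these lists passed. By the mean, the feeding-stimulating, magnocellular, transcription factor, prohormone and GABA and glutamate lists were all inside the range of the means of random lists.

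In the list of releasing hormones and the growth axis the median, 0.11 (random lists -0.21 to 0.04), and the mean, -0.19, differed in sign, and the mean was inside the range of the means of random lists. The growth factor IGF2 was at 4.74 FPKM (0 to 9.49) in the high group and 50.7 FPKM (13.5 to 87.9) in the low group. The rows of IGF2 and IGFBP2 lie on unplaced scaffolds, and that of IGF2 starts at base 1 of its scaffold. Their values are uncertain for that reason. IGF2 and IGFBP2 passed adjusted over the list alone, both with lower values in the high group, and 0 members passed over all rows. IGFBP2 is the same gene that passed in the choroid plexus list (median -0.48), and the fibroblast and meninges list (-1.23) was also lower in the high group. The list members in the fixed set of named genes, the releasing hormones GHRH, CRH and TRH and somatostatin, SST, did not pass. GHRH was at 7.15 against 5.19 FPKM and SST at 156 against 114 FPKM. CRH was at 2.81 against 3.03 FPKM, and TRH differed by a log2 value of 0.04.

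**Figure D2:**
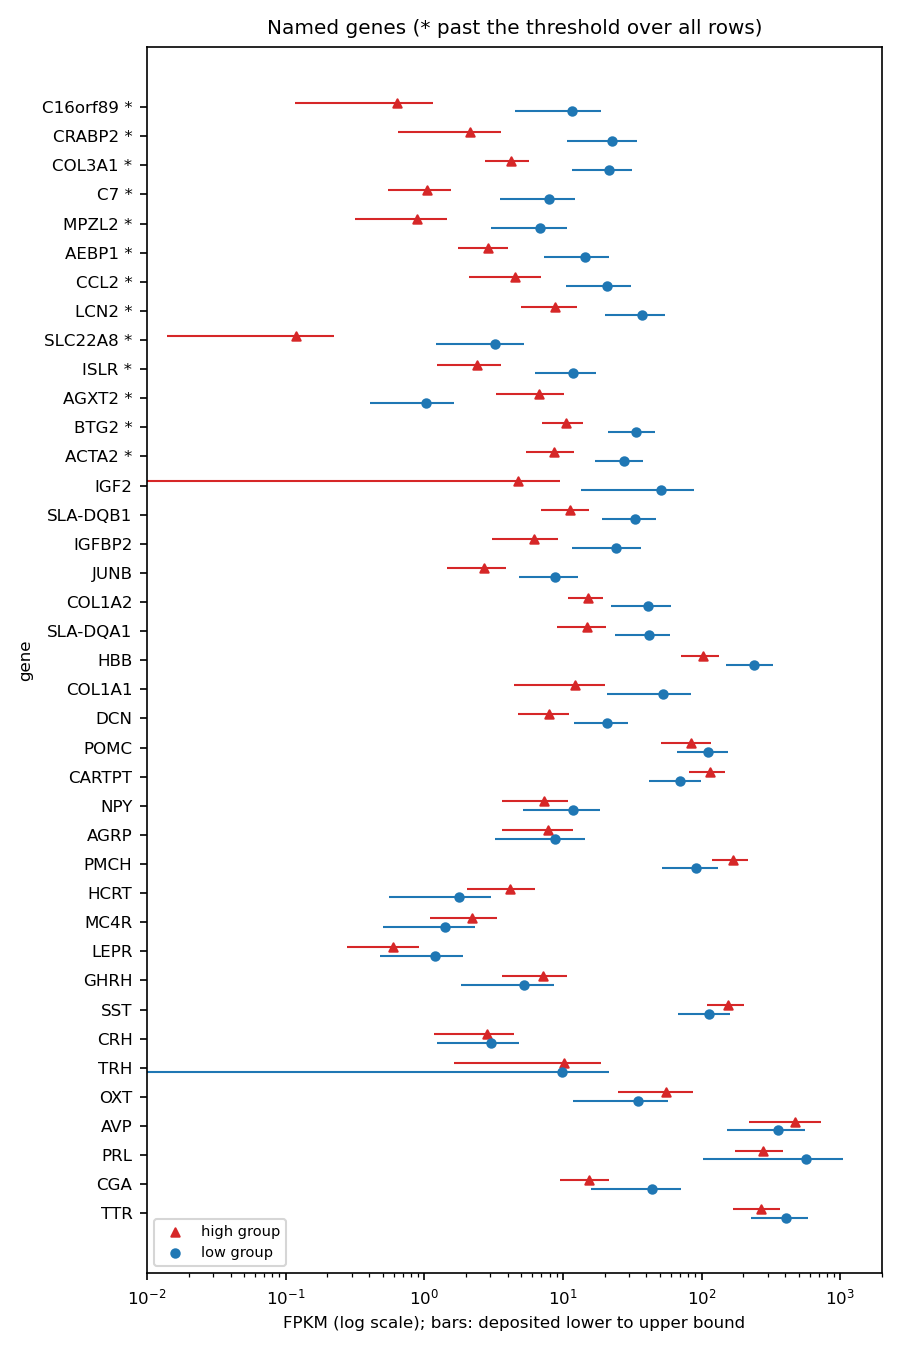
FPKM of each named gene on a log axis, with red triangles for the high group and blue circles for the low group and bars from the deposited lower to the upper bound. Lower bounds of 0 (IGF2 in the high group, TRH in the low group) run to the edge of the axis, and asterisks mark genes past the threshold over all rows, such as COL3A1 at 4.20 and 21.5 FPKM.

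Across the 30 lists, 17 medians were outside the range of random lists, 11 below it and 6 above it. Chance gives 1.5 only for independent genes and lists, whereas genes of a list vary together and some lists share members. Random lists centred below 0, so a list above their range need not differ between the groups. The prohormone list (median 0.02) had 7 members higher and 5 lower in the high group. The GABA and glutamate list (median 0.07) had 3 higher and 3 lower. Set against the means of random lists, 8 means were outside, 8 below and 0 above. Ribosomal protein genes had a median of -0.36 (random lists -0.33 to -0.20), which was inside the range after quantile normalization (-0.08) and by the mean. Medians inside the range were -0.15 for neurons, -0.19 for astrocytes, -0.24 for endothelium, 0.01 for ependymal cells, -0.26 for oxidative phosphorylation and -0.39 for heat shock genes. Those for sterol synthesis (-0.25), fatty acid metabolism (-0.15), core clock genes (-0.06), glucocorticoid-responsive genes (-0.12), thyroid hormone handling and tanycytes (-0.04) and cortex, striatum and thalamus (-0.23) were inside it too. Outside it after quantile normalization were endothelium (-0.17), oxidative phosphorylation (-0.08), heat shock genes (-0.20, and -0.39 without the filter) and thyroid hormone handling and tanycytes (0.15). The medians for neurons, core clock, glucocorticoid-responsive and thyroid genes turned positive under at least 1 scaling. In the cortex, striatum and thalamus list 1 of 6 tested members passed adjusted over the list alone, higher in the low group.

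**Figure D3:**
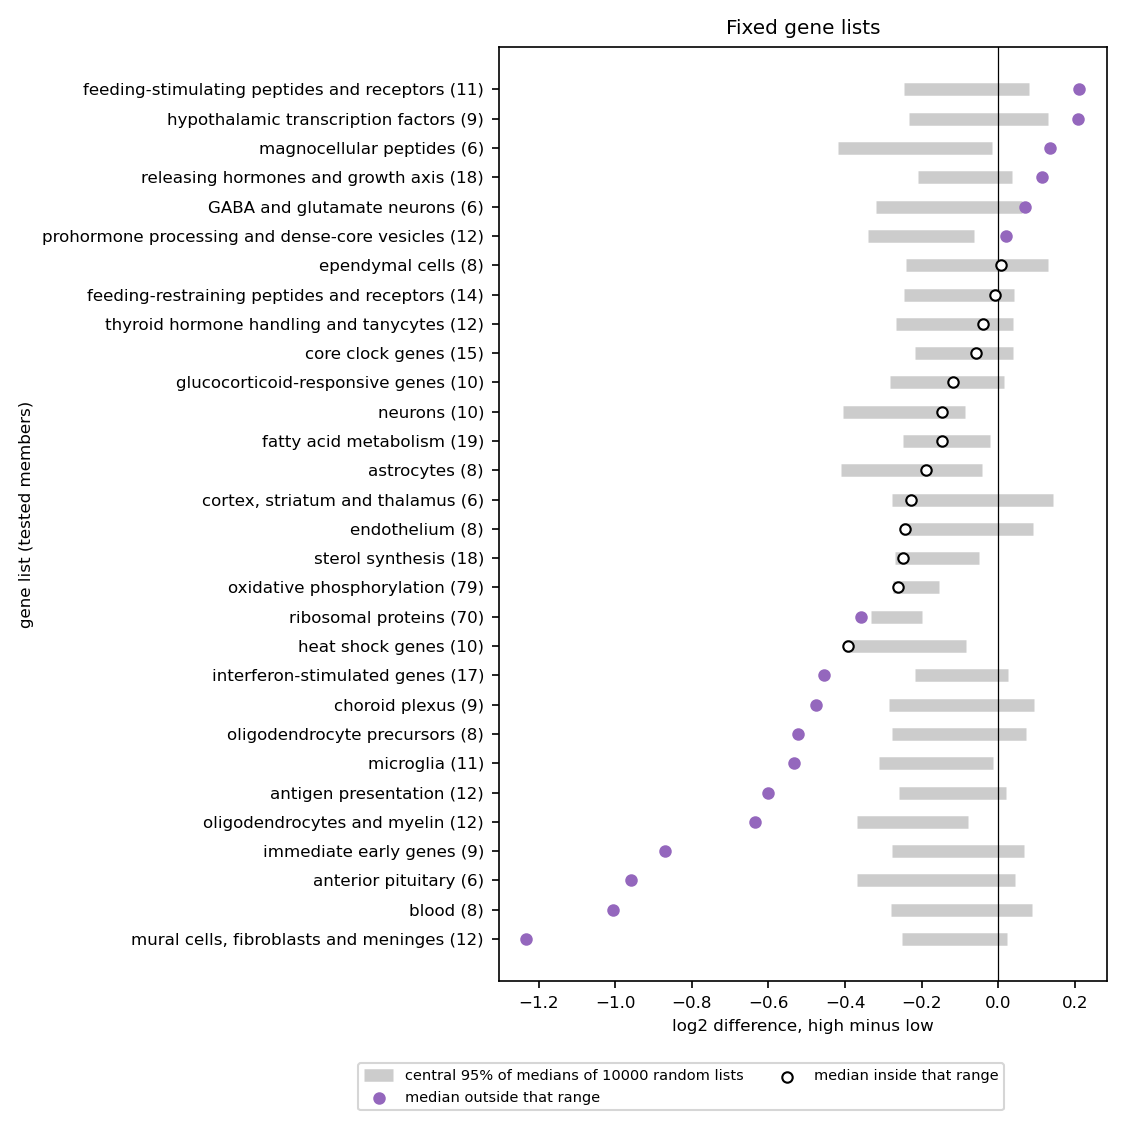
Median log2 difference (high minus low) of each fixed list as a circle, filled where it lay outside the grey bar, which spans the central 95% of medians of 10000 random lists. The fibroblast and meninges list lay lowest at -1.23 and the feeding-stimulating list highest at 0.21.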

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

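The other calling rules, the list means and the lists without called members were chosen after the results were seen. The 32 calls (31 higher in the low group, 1 higher in the high group) became 18 (18 and 0) at a mean of at least 5 FPKM, where fewer rows were tested, and 19 (18 and 1) after either median-of-ratios scaling or quantile normalization. All of these were among the 32. Both scalings moved the median of all tested rows from -0.10 to about 0. Non-overlapping intervals gave 70 (66 and 4), 55 (48 and 7) after median-of-ratios scaling and 53 (47 and 6) after quantile normalization. A threshold of 0.10 gave 40, no filter 30 and 1 row per symbol 26. The 17 lists outside the random range became 8 by the mean (8 lower, 0 higher), and were 17 to 21 under the other settings. The difference of CRH turned to 0.0058 after median-of-ratios scaling, the median of the hypothalamic transcription factor list to -0.013 without a filter, and the releasing hormone and growth axis list to -0.19 by the mean, where IGF2 and IGFBP2 weigh more. Apart from that list and the stricter filter, the cause was not tested. Of the lists, 13 of 30 kept direction and call under every setting compared by list, while 5 lists inside the random range changed sign under some setting. Of 39 named genes, 27 kept both under every setting compared by gene. Neither count covers the mean of at least 5 FPKM. AGXT2, counted among the 27, has a mean of 3.87 FPKM and lost its call there. No paired analysis was possible because the file gives 1 value per group. For the same reason leave-one-out fits, sample weights, the rank-sum test, eBayes variants, covariate fits, camera and fry, list scores, other splits of the animals and a filter on single animals were not run. Depth is unknown, so what it limits could not be measured.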

Other observations

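All tests below were chosen after the patterns were seen, and the second meningeal list was written after the fibroblast pattern but before its own values were looked at.

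By the looser rule of intervals that did not overlap, 4 rows were higher in the high group, and 3 of them, AGXT2, CENPH (5.30 against 1.37 FPKM) and ADAMTS6 (3.17 against 1.15 FPKM), lie on chromosome 16, as do 2 of the 66 rows higher in the low group. After median-of-ratios scaling it was 3 of 7 rows, and after quantile normalization 3 of 6. The other of the 4 was SNCG, at 42.3 against 17.8 FPKM. The genes and the chromosome were picked after their values were seen, so no test of their place was made, and CENPH, ADAMTS6 and SNCG missed the adjusted threshold. Chromosome 16 as a whole had a median of -0.11 over 269 tested rows. The Y-linked genes USP9Y (8.94 against 7.41 FPKM) and EIF1AY (23.6 against 32.8 FPKM) were present in both groups with overlapping intervals.

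Fibroblast and meningeal genes were higher in the low group. Median-of-ratios scaling multiplies all rows of a group by 1 factor, so the list median after it, -1.12, was fixed by that factor. It shows only that a factor of this size is too small to make the pattern. A lower share of neurons alone is argued against for these group values only, since the list lay 1.04 log2 units below the astrocyte list (a difference of -1.04). The bootstrap range, -1.33 to -0.41, was drawn over genes and measures no spread between animals. A second list of 19 tested meningeal fibroblast genes had a median of -0.52 (random lists -0.20 to 0.04), so more meningeal tissue in the samples of the low group may account for part of the pattern, as may a difference in these genes within the tissue. Whether 1 or a few animals carried it cannot be told apart, because values per animal were not used and level largely sets the width of the bounds (ratio of widths 1.1, bootstrap range 0.996 to 1.26). A link to growth and fatness stays open and untested.

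Myelin genes were also higher in the low group. Median-of-ratios scaling left the list median at -0.52, a result again fixed by its 1 factor. That factor is too small to make the pattern. A lower share of neurons alone is argued against, for these group values only, by a difference of -0.45 from the astrocyte list. The bootstrap range, -0.70 to -0.30, was again drawn over genes and not over animals. By the mean the list was inside the range of the means of random lists, so its call depends on the statistic. Extreme rows can widen a range of means more than a range of medians, and whether they did was not tested. All 12 tested members were higher in the low group. Where the tissue was taken within the region and the growth and fatness of the animals may each have a part, and neither was tested.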
